A study of Mus musculus with 6 samples.

How the data were processed

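RNA from 6 mice with lung cancer was sequenced, 3 mice treated with artemisinin and 3 untreated model mice. Per the labels' protocols, total RNA was extracted with the mirVana kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool, the annotation and the strand setting of the counting were not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour may not have been told apart. The labels give the groups and number the mice 1 to 3 within each. The design text calls the samples mice, so each library was taken as 1 mouse.

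The authors deposited a table of read counts per gene, whole numbers without normalization, and a table of FPKM, counts scaled by gene length and library total. Both tables hold the same 18238 genes and 6 libraries, and every column of values belonged to 1 of the 6 mice. Checked against the count table, the deposited FPKM were the same counts divided by each library's total and a value per gene, with a largest relative gap of 3.2e-07 over 15462 genes, so the FPKM are not independent evidence. Each gene had an Entrez number, and 18124 of these matched the reference gene table of GRCm38.p6, from which coordinates were taken. The table held 1 gene of the Y chromosome, with at most 10 counts in a library.

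Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, which kept 15242 genes, TMM factors (0.948 to 1.06), estimateDisp, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F value. Normalised CPM are counts scaled to the library total times its TMM factor, given as mean ± SD over n = 3 mice, and values of genes outside the filter are CPM of the plain total. Where a group had 1 to 3 counts of a gene in all, the ratio of rates is given with its exact binomial 95% interval in place of the fitted fold. Comparisons of 3 against 3 cannot go below an exact two-sided p of 0.1 by permutation, so the p-values rest on the model's spread shared across genes. The FPKM table was tested with limma 3.58.1 (trend) on log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, a scale that understates the change of low genes.

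The main design, the named genes, all lists and most alternatives were choices made before the data were examined. There were 23 program lists and 24 cell type lists, with 732 entries, of which 716 matched a gene in the table, 2 by an older symbol. They were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the 46 lists that had at least 3 tested members. Camera with an estimated correlation and fry, a test of whether a list moves on balance in 1 direction, were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone. Lists share some genes, such as Vegfa. In 8 lists that were not called (endothelium, macrophages, erythroid cells, hypoxia and glycolysis, haem synthesis, DNA replication, NRF2 targets, and p53 targets and apoptosis) the median, the mean and the test were not all of 1 sign. List medians were the same with genes at 1 to 3 counts in a group set to the bound of their counting interval.

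The genes to be named were fixed by rule: the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM, separated groups and a symbol that is not a clone name, a predicted gene or a pseudogene; the 4 members with the smallest p in each called list; and a set named whatever its result, which is Tfrc, Fth1, Slc7a11, Gpx4, Hmox1, Acsl4, Mki67, Vegfa, Egfr, Trp53, Ctnnb1, Cdkn1a, Sftpc, Scgb1a1, Krt5, Pecam1, Ptprc, Col1a1, Acta1 and Hbb-bs. 1 gene that this rule names is not reported here. Further genes named are called members of the fixed lists or were chosen after their values were seen, as Trim12c was.

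The fits were tested on simulated counts drawn from these libraries' means and sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For this comparison edgeR recovered 28% of the 2-fold and 83% of the 4-fold changes, with 8.26% of its calls false over 15100 genes. DESeq2 recovered 51% and 91% over 15242 genes, with 26.8% of its calls false. Limma-voom recovered 25% and 78% over 15100 genes, and limma on scaled values 26% and 80% over 14873 genes. Camera called 2 of 2 changed lists and 0 of the others. The simulated genes were drawn independently, so this could not check the preset correlation of 0.01. Both simulated groups also had the same spread for each gene. In the data the biological coefficient of variation was 0.389 within the artemisinin group and 0.211 within the model group. The simulated rates therefore do not cover unequal spread. In the data the estimated correlation was 0.758 for the alveolar type 2 list.

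The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals alone, no filter, a filter of 1 CPM in 3 libraries, no robust estimation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, other list tests, another pseudocount or no filter for FPKM, and each library left out in turn. With a library left out the expression filter was run again, and edgeR then tested between 15397 and 15537 genes. The members of a list could therefore differ between these fits and the main fit. Limma-voom with library weights, fry's mixed test and gene ontology terms from the count table were added after the data were examined. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.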

Results

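Gene expression was measured by RNA-seq in 6 mice with lung cancer, 3 treated with artemisinin (artemisinin replicates 1 to 3) and 3 left as the untreated model (model replicates 1 to 3). Artemisinin is a sesquiterpene lactone with an endoperoxide bridge, first isolated from Artemisia annua and used against malaria. The tissue, the strain, the dose, the duration of treatment and the time of day of collection were not given in the sources used here. The most abundant transcript in every library was one of lung epithelium. Scgb1a1, the secretory protein of club cells, led all 3 artemisinin libraries, and Sftpc, the surfactant protein C gene of alveolar type 2 cells, led all 3 model libraries. The libraries held 25566173, 32108455 and 33126585 counts in the artemisinin mice and 34745497, 32964061 and 33074884 in the model mice, with between 16566 and 17015 genes detected in each. A gene with 3 counts in the smallest library stood at 0.117 CPM.

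The model libraries resembled each other more closely than the artemisinin libraries did. Spearman correlations of log2 CPM across genes ranged from 0.986 to 0.991 within the model group, from 0.945 to 0.967 within the artemisinin group and from 0.939 to 0.971 between the groups. The biological coefficient of variation was 0.389 within the artemisinin group and 0.211 within the model group. The first principal component held 50.1% of the variance and separated the groups, and the second, with 20.5%, set artemisinin replicate 2 apart. That library had the highest levels of the skeletal muscle and keratinocyte markers. The skeletal actin gene Acta1 reached 2646 CPM in artemisinin replicate 2 and at most 0.978 CPM in the other 5 libraries, and the basal keratin gene Krt5 reached 150.1 CPM against at most 2.03. Both genes were therefore removed by the expression filter and were not tested. Artemisinin replicate 1 gave 7.07% of its counts to Scgb1a1, against 0.68% to 2.56% in the other libraries.

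The comparison of artemisinin with the model asked which genes related to lung cancer change their expression under the drug. Genes that fell with artemisinin included 7 of 12 alveolar type 2 markers and the single genes Ros1, Cldn2 and Gjb1. Genes that rose included the neutrophil granule genes Camp, Ngp and Ltf, the contractile smooth muscle genes Acta2 and Cnn1, and the complement protease gene C1rb. No gene list was called by camera with an estimated correlation. Sftpa1, which encodes surfactant protein A, fell from 12439 ± 1309 to 2189 ± 1014 normalised CPM (SD, n = 3 per group). Acta2, the smooth muscle actin gene, rose from 81.8 ± 12.3 to 341.3 ± 75.9 normalised CPM (SD, n = 3 per group). Of 15242 genes tested, 331 were higher and 351 lower with artemisinin at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 253 and 272 of them by at least 2-fold. Without adjustment, 3758 genes had p under 0.05, where 762 were expected by chance. In all 682 called genes the 3 artemisinin values lay entirely above or below the 3 model values. Over all tested genes this held for 33.6%, where chance gives 10%.

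These counts changed with each library left out, and were lowest when any 1 of the model replicates was left out. Each such fit also has fewer mice, so a lost call need not come from the library left out. Without artemisinin replicate 1, 2 or 3 edgeR called 169, 670 and 276 genes higher and 140, 713 and 218 lower, and without model replicate 1, 2 or 3 it called 6, 39 and 8 higher and 11, 79 and 15 lower. With scaling by library totals alone, the split of 331 higher against 351 lower became 464 against 319. That scaling moved the median log2 fold change of all genes from 0.04 to 0.15. DESeq2 called 1251 genes higher and 1035 lower. Cldn2, Gjb1, Trim12a and C1rb kept an edgeR, DESeq2 or limma adjusted p under 0.05 in all 17 alternative settings run. Of the 24 named genes with the largest changes edgeR kept 16, 24 and 19 without artemisinin replicate 1, 2 or 3 and 4, 8 and 5 without model replicate 1, 2 or 3.

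The 12 genes with the largest falls included genes of epithelial junctions and signalling. Ros1, a receptor tyrosine kinase gene rearranged in some human lung cancers (chromosome 10, 52044863 to 52195398, GRCm38), fell from 114.3 ± 58.8 to 2.21 ± 1.73 normalised CPM (SD, n = 3 per group), a log2 fold change of −5.70 ± 0.71 (SE; edgeR adjusted p = 0.0139). Cldn2, which encodes a pore-forming claudin of tight junctions (chromosome X, 139800808 to 139811386), fell from 39.8 ± 10.8 to 0.706 ± 0.232 normalised CPM, 55.4-fold (log2 −5.79 ± 0.34, SE; edgeR adjusted p = 0.00233). The connexin genes Gjb1 and Gja3 fell 16.7-fold and 108-fold. Cltrn fell with a log2 fold change of −7.61 ± 1.25 (SE), from model values spread at 13.2 ± 14.8 normalised CPM (SD, n = 3). The plasma protein genes Fga, Fgg and Alb fell, with model means of 3.87, 6.66 and 10.3 normalised CPM. Fga had 2 counts in the artemisinin libraries together against 377 in the model libraries, a ratio of rates of 170 with an exact binomial 95% interval of 46.7 to 1407 that covers counting error only. The Fga ratio was 110 (30.2 to 910) without artemisinin replicate 2, and the Fga call was lost without model replicate 1 or 3. Spag11b, Cyp2c40 and Rims1 fell by 26.2-fold, 55.7-fold and 18.8-fold. All artemisinin counts of Cyp2c40 came from replicate 3, and without it Cyp2c40 was at least 108-fold lower, against a floor of 3 counts over the group. Of the 12 largest falls only Trim12a, Cldn2 and Gjb1 were still called without model replicate 1, so Ros1 also lost its call. The log2 fold changes of Cltrn, Gja3 and Alb were then −6.12, −6.09 and −3.86. Without artemisinin replicate 1 that of Fgg was −5.30, and without artemisinin replicate 2 those of Ros1 and Rims1 were −6.50 and −4.85. With 3 artemisinin counts left without replicate 1 the ratio for Gja3 was 284 (96.9 to 1379), and with 1 left without replicate 2 the ratio for Cltrn was 756 (135 to 29879).

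The largest fall belonged to Trim12a, a gene of the Trim5 family of antiviral factors (chromosome 7, 104299893 to 104315558, GRCm38, protein coding). It had 456, 537 and 496 counts in the model libraries and 0, 0 and 1 in the artemisinin libraries. The ratio of rates was 1342, with an exact binomial 95% interval of 240 to 53022 for counting error only (edgeR adjusted p = 0.00233). Without artemisinin replicate 2 the ratio was 867 (155 to 34273), and without artemisinin replicate 3, which held the only count, Trim12a was at least 284-fold lower, against a floor of 3 counts over the group. Its neighbour and close paralog Trim12c fell from 36.4 ± 4.55 to 13.9 ± 0.955 normalised CPM (SD, n = 3 per group; log2 −1.39 ± 0.16, SE; edgeR adjusted p = 0.0113). Reads of such paralogs may be split or lost in the counting, so the levels of Trim12a and Trim12c, of the stefin genes and of C1rb are less certain than those of single-copy genes.

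The 12 largest rises were led by genes of neutrophils and their precursors. Camp, the cathelicidin gene, rose from 1.31 ± 0.794 to 104 ± 116 normalised CPM (SD, n = 3 per group), 79.4-fold (edgeR adjusted p = 0.0251). Its artemisinin values were 29.7, 44.1 and 238.1 normalised CPM, all above the highest model value of 2.19. Ngp and Ltf, which encode further granule proteins, and Prtn3, the proteinase 3 gene, rose with log2 fold changes of 5.88 ± 1.14, 4.81 ± 0.79 and 6.23 ± 1.09 (SE). The stefin family genes Stfa1 and Cstdc5 rose 122.8-fold and 131.6-fold, with model means of 0.0508 and 0.0923 normalised CPM. Stfa3 and the integrin gene Itgb2l had 2 counts each in the model libraries together, against 475 and 691 in the artemisinin libraries. Their ratios of rates were 264 (exact binomial 95% interval 72.6 to 2183) and 383 (106 to 3173), again for counting error only. Artemisinin replicate 3 held most of these counts, and without it the ratios were 69.0 (18.5 to 580) and 73.4 (19.7 to 616). Without model replicate 1 the ratio for Stfa3 was 173 (47.6 to 1430), and Itgb2l had 0 model counts and was at least 168-fold higher, against a floor of 3 counts over the group. Neither gene was called with any 1 model replicate left out, nor was Itgb2l without artemisinin replicate 1. C1rb, a gene for the complement protease C1r (chromosome 6, 124570430 to 124581044, GRCm38), rose 43.7-fold to 9.17 ± 2.99 normalised CPM (SD, n = 3; edgeR adjusted p = 0.00553). The neighbouring complement genes C1ra and C1s1 had log2 fold changes of 0.12 ± 0.13 and 0.24 ± 0.15 (SE). Neither was called (edgeR adjusted p = 0.582 and 0.364). Pianp, on the same chromosome at 124996720 to 125003096, rose 33.3-fold. Smpx, a small muscle protein gene, rose 67.1-fold and Aqp7, an aquaglyceroporin gene of fat cells, rose 51.6-fold. For Smpx the log2 fold change was 6.07, and 4.52 without artemisinin replicate 2, and for Aqp7 it was 5.69, and 4.55 and not called without artemisinin replicate 1. Without artemisinin replicate 3 the log2 fold changes of Camp, Prtn3, Ltf and Stfa1 were 4.77, 4.33, 3.66 and 5.77, and those of Ngp and Cstdc5 were 4.53 and 6.23 and not called. Stfa1 and Cstdc5 were also not called with any 1 model replicate left out. With 1 model count left without model replicate 1 the ratio for Stfa1 was 496 (88.7 to 19620), and with 2 left without model replicate 2 that for Cstdc5 was 477 (132 to 3942). Without model replicate 2 the log2 fold change of Pianp was 5.71. Of the 12 largest rises only C1rb was still called without model replicate 1.

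**Figure D1:**
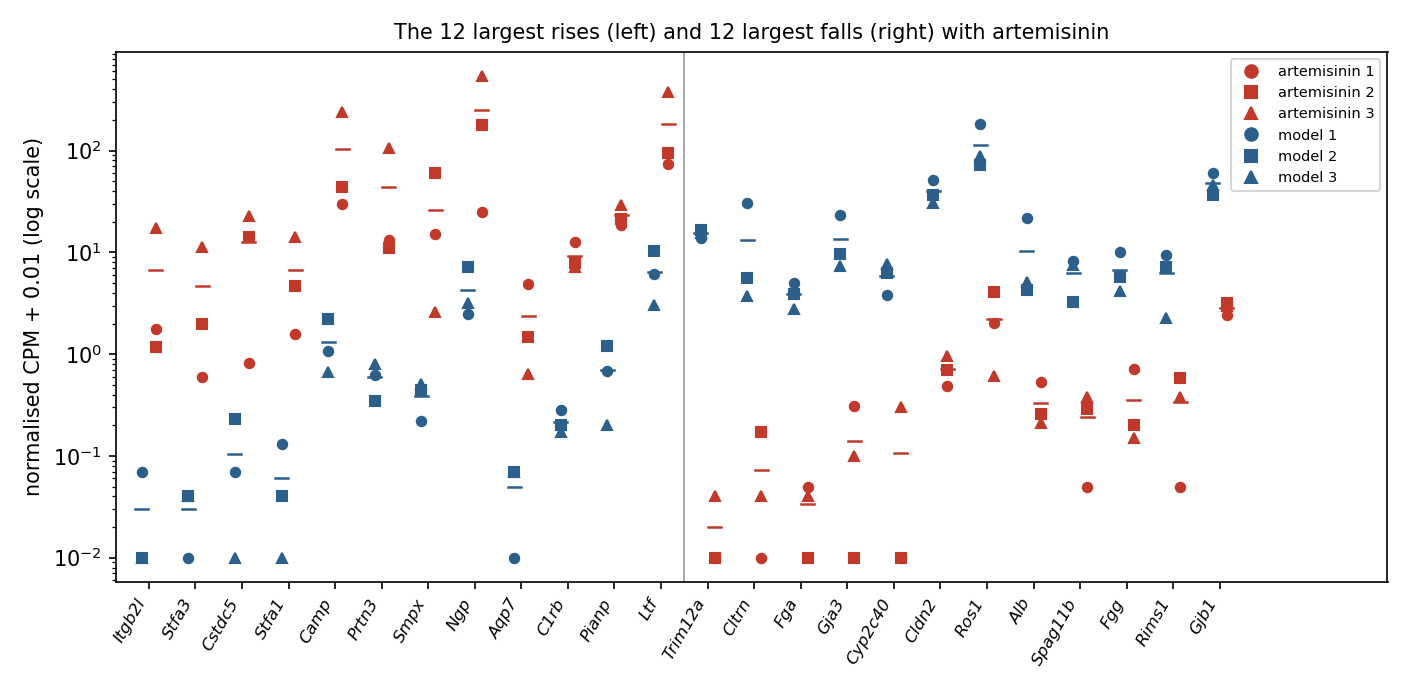
Normalised CPM plus 0.01 on a log axis for the 12 genes with the largest rises and the 12 with the largest falls, in each of the 6 libraries (red, artemisinin; blue, model; shapes give the replicate, short lines the group mean). The rule that chose these genes required the 3 artemisinin points to lie on 1 side of the 3 model points. The artemisinin points of the neutrophil genes spread widely, as for Camp from 29.7 to 238.1 normalised CPM.

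Cell type markers were tested as lists. Camera with a preset correlation of 0.01 called 11 of 23 cell type lists, 9 higher and 2 lower, with adjustment over all 46 lists tested. None of them was called by camera with an estimated correlation or by fry, where 2 and 7 cell type lists had an unadjusted p under 0.05. For each called list the estimated correlation gave the highest adjusted p of the alternatives run. All 12 alveolar type 2 markers were below 0, with a median log2 fold change of −2.06 (camera adjusted p = 4.01e-20; adjusted p = 0.526 with an estimated correlation). Of these, 7 fell at an adjusted p over all genes and 12 when adjusted over the list alone. Sftpb, the surfactant protein B gene, fell from 8301 ± 2010 to 1585 ± 607.9 normalised CPM (SD, n = 3 per group; log2 −2.39 ± 0.38, SE; edgeR adjusted p = 0.0245). Napsa and Chil1 fell 3.66-fold and 4.39-fold. Sftpc was 27849 ± 6873 in the model and 7971 ± 4375 normalised CPM with artemisinin, a difference that missed the threshold over all genes (log2 −1.80 ± 0.54, SE; edgeR adjusted p = 0.104). The 10 alveolar type 1 markers had a median of −0.08 (camera adjusted p = 0.575), and 0 of them changed over all genes or when adjusted over the list alone. The type 2 median stayed between −1.85 and −2.24 when any 1 library was left out.

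Airway markers had positive medians. The 12 ciliated cell markers were all above 0, with a median of 1.30 (camera adjusted p = 8.67e-05; adjusted p = 0.570 with an estimated correlation). None of them passed over all genes, and 9 rose when adjusted over the list alone. The mean ciliated level relative to the model mean was 1.79, 0.44 and 1.31 on the log2 scale in artemisinin replicates 1, 2 and 3. The groups overlapped, as model replicate 2 stood at 0.52. Tekt4, a tektin of the ciliary axoneme, had 4.95 ± 1.42 normalised CPM in the model and 15.3 ± 7.64 with artemisinin (SD, n = 3 per group). The 10 club and secretory markers had a median of 1.61 and no call (camera adjusted p = 0.224), with no member that changed over all genes or when adjusted over the list alone. Their library means ranged from −1.61 in artemisinin replicate 2 to 2.38 in artemisinin replicate 1, relative to the model mean on the log2 scale. Scgb1a1 had 12178 ± 5252 normalised CPM in the model and 36470 ± 26388 with artemisinin (edgeR adjusted p = 0.168).

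Neutrophil markers were higher in all 3 artemisinin mice. All 13 were above 0, with a median of 4.66 (camera adjusted p = 1.61e-12; adjusted p = 0.526 with an estimated correlation). Of these, 6 rose over all genes and 13 when adjusted over the list alone. S100a9, a calprotectin subunit gene, rose from 49.1 ± 8.97 to 884.6 ± 879.2 normalised CPM (SD, n = 3 per group; log2 4.17 ± 0.72, SE; edgeR adjusted p = 0.0278). Ly6g, a surface marker of mouse neutrophils, rose 27.1-fold. Without artemisinin replicate 3, which had the highest levels, the list median was 3.10 and the log2 fold changes of S100a9 and Ly6g were 2.90 and 3.78. Markers of platelets and megakaryocytes had a median of 2.62 (camera adjusted p = 1.42e-04; adjusted p = 0.570 with an estimated correlation), with 0 of 10 called over all genes, 9 when adjusted over the list alone, and a median of 1.55 without artemisinin replicate 1. Gp1bb, a platelet glycoprotein gene, had 0.434 ± 0.284 normalised CPM in the model and 6.46 ± 6.40 with artemisinin.

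T cell and B cell markers had medians of 0.67 and 0.68, each with a camera adjusted p = 0.0435, and adjusted p = 0.795 and 0.758 with an estimated correlation. No member passed over all genes or when adjusted over the list alone. The T cell call was lost without artemisinin replicate 1 or 3 or model replicate 1 or 3, and the B cell call without artemisinin replicate 1 or 3 or model replicate 1. Both calls were also lost with scaling by library totals (adjusted p = 0.0705 each) and with the replicate number as a block (0.0679 for T cells and 0.0755 for B cells). The T cell and B cell medians were 0.34 and 0.39 without artemisinin replicate 3. Among 14 macrophage markers the median was 0.00125, with a mean of −0.07 (camera adjusted p = 0.907). Within that list Csf1r, the receptor gene for macrophage colony-stimulating factor, rose from 118 ± 4.22 to 215.6 ± 13.2 normalised CPM (SD, n = 3 per group), and Marco, a scavenger receptor of alveolar macrophages, fell from 30.6 ± 15.0 to 5.42 ± 1.69, and when adjusted over the list alone 1 rose and 2 fell. Dendritic cell, cytotoxic cell, mast cell and eosinophil, and erythroid lists had medians of 0.41, 0.41, −0.54 and 0.52, where the erythroid test pointed lower with a mean of 0.05, and no member that changed over all genes or when adjusted over the list alone, and none was called (camera adjusted p = 0.146, 0.165, 0.415 and 0.994).

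Contractile genes of smooth muscle rose. All 9 markers were above 0 and 7 rose, over all genes and when adjusted over the list alone, with a median of 1.92 (camera adjusted p = 4.80e-13; adjusted p = 0.526 with an estimated correlation). Acta2 rose 4.17-fold (log2 2.06 ± 0.22, SE; edgeR adjusted p = 0.00984), and Actg2, Cnn1 and Tagln rose 8.91-fold, 6.28-fold and 3.59-fold. Fibroblast and pericyte markers had a median of 0.80 (camera adjusted p = 0.00154; adjusted p = 0.526 with an estimated correlation). Of these 12, 1 rose over all genes, the pericyte proteoglycan gene Cspg4 at 2.22-fold, and 6 rose when adjusted over the list alone. Tcf21, Col13a1 and Thy1 had log2 fold changes of 1.04, 0.95 and 0.73 that missed the threshold. Endothelial markers had a median of −0.01 and a mean of 0.09, with no call (camera adjusted p = 0.849) and no member that changed over all genes or when adjusted over the list alone. The mesothelial list had a median of 0.53 and the Schwann cell and neuron list 0.14, neither called (camera adjusted p = 0.907 and 0.116), with 0 members changed over all genes and 0 and 3 risen when adjusted over the list alone.

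Skeletal muscle markers stood highest in artemisinin replicate 2, and cardiac and fat markers in artemisinin replicate 1. The 7 tested skeletal muscle markers had a median of 6.32 (camera adjusted p = 0.00992; adjusted p = 0.742 with an estimated correlation), and 1.22 without artemisinin replicate 2. The filter was run again without that replicate, so the members behind the median of 1.22 may differ from the 7. With the replicate number as a block the skeletal muscle median was 2.85. In the main fit none of the 7 passed over all genes, and 7 rose when adjusted over the list alone. Tnnt3, the fast skeletal troponin T gene, stood at 813 normalised CPM in artemisinin replicate 2 and at 20.8 and 3.64 in replicates 1 and 3. Ckm, Mb and Ryr1 had log2 fold changes of 7.36 ± 1.96, 5.65 ± 1.48 and 4.17 ± 1.28 (SE). Among 10 cardiac markers Actc1 rose and Myh7 fell, by log2 values of 2.70 and −2.07, and the list was not called (median 2.46, camera adjusted p = 0.0945). When adjusted over the list alone 5 cardiac markers rose and 1 fell. The mean level of the cardiac list relative to the model mean was 3.16, −0.34 and 0.92 on the log2 scale in artemisinin replicates 1, 2 and 3. Adipocyte markers had a median of 2.52 (camera adjusted p = 0.00154; adjusted p = 0.570 with an estimated correlation), and 1.44 without artemisinin replicate 1. The lipid droplet gene Plin4 rose 4.77-fold, the only 1 of 10 over all genes, and 6 rose when adjusted over the list alone. Fabp4 had 303.1 normalised CPM in artemisinin replicate 1 and 56.2 and 37.2 in replicates 2 and 3.

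Hepatocyte markers were present at low levels and went in both directions. The median of 6 was −2.50, with 2 of them above 0 (camera adjusted p = 0.0182; adjusted p = 0.547 with an estimated correlation). Fga and Alb fell over all genes. When adjusted over the list alone 3 fell and 1 rose, the cytochrome P450 gene Cyp2e1 at a log2 fold change of 2.71 (edgeR adjusted p over all genes = 0.0552). The call was lost without artemisinin replicate 2, where the hepatocyte median was −1.07, and this median was −1.45, −1.28 and −1.61 without artemisinin replicate 1 or 3 or model replicate 1. The filter was run again in each of these fits, so the members behind these medians may differ from the 6 above. The 5 tested keratinocyte markers had a median of 2.50 and no call (camera adjusted p = 0.408), and 0 changed over all genes, while 3 rose and 1 fell when adjusted over the list alone. Only 2 melanocyte markers passed the expression filter, Mlana and Mitf with log2 fold changes of −2.04 and −0.82 that missed the threshold over all genes, so that list was not tested.

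**Figure D2:**
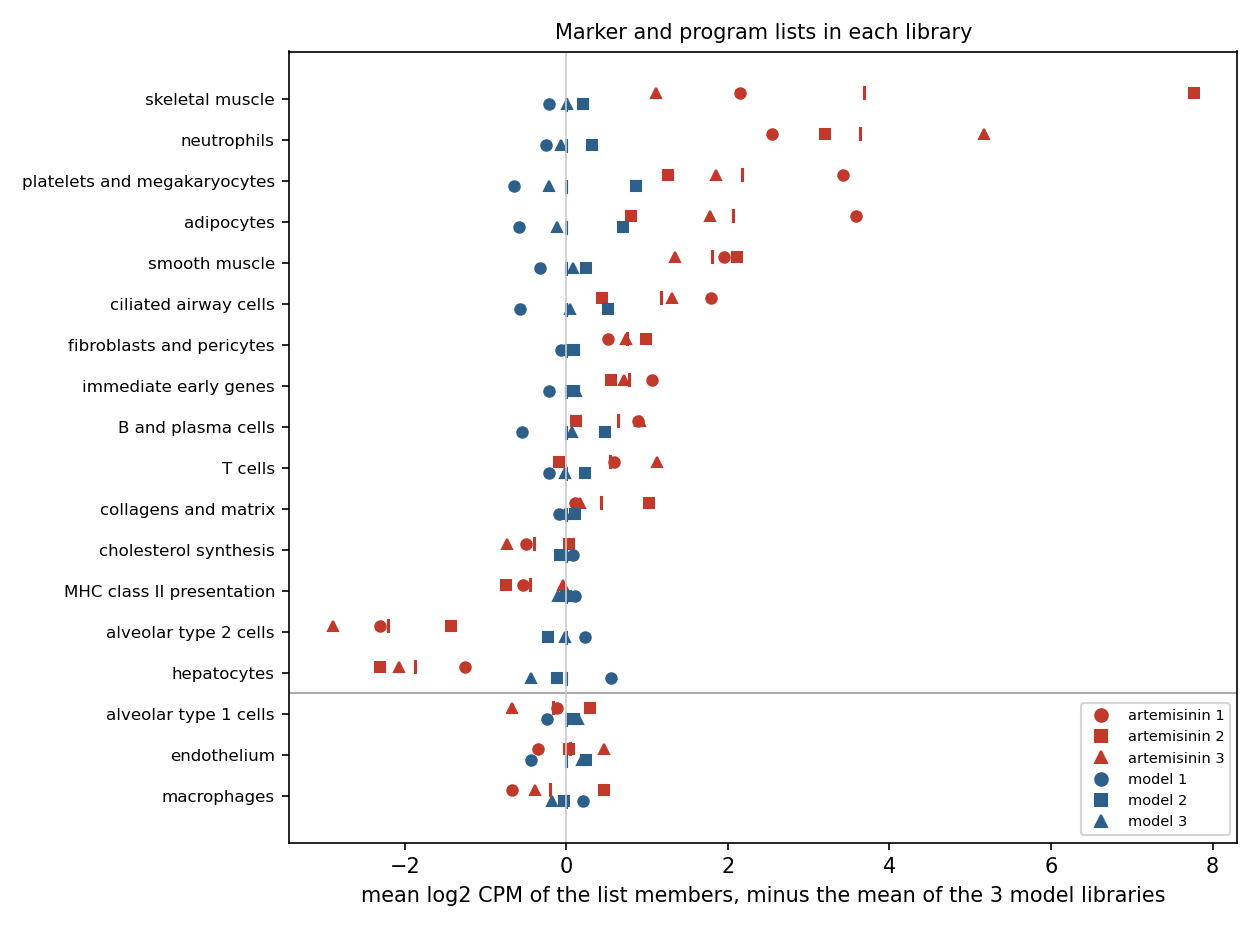
Mean log2 CPM of the members of each called list, and below the line of 3 lists that were not called, in each library relative to the mean of the 3 model libraries (red, artemisinin; blue, model; shapes give the replicate, short lines the group mean). Alveolar type 2 markers lie at −2.30, −1.43 and −2.89 and neutrophil markers at 2.54, 3.20 and 5.17 in artemisinin replicates 1, 2 and 3, and skeletal muscle markers reach 7.77 in replicate 2.

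Among the 23 program lists, camera called 4, 2 higher and 2 lower. With an estimated correlation or by fry it was 0, and 0 and 6 had an unadjusted p under 0.05. Immediate early genes, which respond within minutes to stimuli, were all above 0, with a median of 0.72 over 19 members (camera adjusted p = 4.48e-06; adjusted p = 0.526 with an estimated correlation). Dusp1, Zfp36 and Nr4a1 rose 2.41-fold, 2.35-fold and 2.87-fold (edgeR adjusted p = 0.0356, 0.0394 and 0.0408), and 7 rose when adjusted over the list alone. Egr1 had a log2 fold change of 1.02 ± 0.27 (SE) that missed the threshold (edgeR adjusted p = 0.0819). Collagens and matrix genes had a median of 0.53 (camera adjusted p = 0.00205; adjusted p = 0.742 with an estimated correlation). Of these 22, Lox, the collagen cross-linking enzyme, rose 2.94-fold, and it was also the 1 that rose when adjusted over the list alone. Col6a1, Col6a2 and Loxl1 had log2 fold changes of 0.60, 0.69 and 0.64 that missed the threshold. Without artemisinin replicate 2 the median was 0.18 and the call was lost.

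Cholesterol synthesis genes had a median of −0.30 over 19 members (camera adjusted p = 0.00913; adjusted p = 0.758 with an estimated correlation), with none called over all genes or when adjusted over the list alone. Lss, Insig1 and Stard4 had log2 fold changes of −0.78, −0.54 and −0.71. The call was lost without artemisinin replicate 3, and the median was −0.57 without artemisinin replicate 2. Class II antigen presentation genes had a median of −0.46 over 10 members (camera adjusted p = 0.0177; adjusted p = 0.742 with an estimated correlation). H2-DMb1, a peptide loading gene, fell 2.10-fold, and was the 1 member that fell over all genes and when adjusted over the list alone. Cd74, the invariant chain gene, was 2989 ± 411.8 in the model and 1411 ± 586 normalised CPM with artemisinin (SD, n = 3 per group; edgeR adjusted p = 0.110), and H2-Aa and H2-DMa had log2 fold changes of −0.64 and −0.42. The call was lost without artemisinin replicate 2, and the median was −0.72 without artemisinin replicate 3.

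Lung cancer genes went in both directions. Of 26 tested, Ros1, Met and Erbb3 fell and Fgfr1 and Sox2 rose over all genes, and 5 fell and 2 rose when adjusted over the list alone. Met, the hepatocyte growth factor receptor gene, fell from 170 ± 5.47 to 49.7 ± 20.9 normalised CPM (SD, n = 3 per group; log2 −1.78 ± 0.29, SE; edgeR adjusted p = 0.0256). Fgfr1 rose from 40.7 ± 7.10 to 76.2 ± 7.68. The list as a whole was not called (median −0.17, camera adjusted p = 0.116). Among epithelial-mesenchymal transition genes S100a4, Tgfbi and Snai2 rose by log2 values of 2.31, 1.01 and 1.03 and Epcam fell by 1.34, over all genes and when adjusted over the list alone (median 0.37, camera adjusted p = 0.0945). Among inflammatory cytokine genes of the NF-kB response Nfkbia, Nfkbiz and Ccl2 rose by 0.85, 1.23 and 1.97, and 4 rose when adjusted over the list alone (median 0.85, camera adjusted p = 0.0815). Clock genes went in both directions, with Dbp and Nr1d1 higher by 2.14 and 1.37 and Npas2 and Arntl lower at −1.29 and −0.74 (median 0.47, camera adjusted p = 0.116), and 6 rose and 2 fell when adjusted over the list alone. Camera asks for a shift in 1 direction, so it cannot decide on opposite changes within a list. The time of day of collection was not given for either group, which leaves the meaning of the clock gene changes open.

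Acsl4, a lipid enzyme of ferroptosis, fell from 495.2 ± 76.9 to 155.7 ± 76.3 normalised CPM (SD, n = 3 per group; log2 −1.67 ± 0.34, SE; edgeR adjusted p = 0.0425). The Acsl4 call was kept in 10 of 17 alternative settings. Its fall lay within the range of the alveolar type 2 markers, −2.85 to −1.39, and a link to them was not tested. In the iron handling and ferroptosis list of 24, the transferrin gene Trf fell as well, at −2.52 (−1.91 and not called without model replicate 1), and 3 fell and 1 rose when adjusted over the list alone (median −0.11, camera adjusted p = 0.120). The iron and ferroptosis genes Tfrc, Fth1, Slc7a11, Gpx4 and Hmox1 had log2 fold changes of −0.81 ± 0.26, 0.31 ± 0.20, −0.36 ± 0.46, 0.20 ± 0.24 and −0.48 ± 0.19 (SE) and did not pass. Without artemisinin replicate 1 Slc7a11 and Gpx4 had the other sign, at 0.0235 and −0.0823. In the beta-catenin target list Rnf43 and Sp5 fell by 0.89 and 2.98, with 3 that fell when adjusted over the list alone (median −0.27, camera adjusted p = 0.232). Ctnnb1, which encodes beta-catenin, had a log2 fold change of −0.99 ± 0.26 (SE; edgeR adjusted p = 0.0776).

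Proliferation and cell death lists were not called. The cell cycle list had a median of −0.21 with 0 of 22 members changed (camera adjusted p = 0.408), and DNA replication had 0.04, with a mean of −0.00369 and 0 of 22 changed (camera adjusted p = 0.827). No member of either list changed when adjusted over the list alone. Mki67 had a log2 fold change of 0.30 ± 0.29 (SE), and −0.0143 without artemisinin replicate 3. In the list of p53 targets and apoptosis Bcl2, an inhibitor of apoptosis, rose 1.92-fold, the 1 of 23 that changed, also when adjusted over the list alone, and the median was 0.03 with the test pointing lower (camera adjusted p = 0.994). Trp53 and Cdkn1a had log2 fold changes of 0.11 ± 0.13 and −0.08 ± 0.19 (SE), and Vegfa and Egfr of 0.57 ± 0.34 and 0.37 ± 0.36. The sign of Cdkn1a turned with scaling by library totals, at 0.0183, and without artemisinin replicate 1, at 0.0716. In the hypoxia and glycolysis list Ndrg1 rose 1.75-fold (median −0.000823, mean 0.14, camera adjusted p = 0.724, 3 risen when adjusted over the list alone), in the haem synthesis list Cpox fell 2.29-fold (median −0.14, mean 0.04, camera adjusted p = 0.734, 1 fallen when adjusted over the list alone), and in the interferon list Oasl1 rose 2.72-fold (median 0.15, camera adjusted p = 0.238, 2 risen when adjusted over the list alone).

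The remaining programs had no member past the threshold over all genes. Their medians were 0.21 for oxidative phosphorylation, 0.59 for immune checkpoints, 0.26 for xenobiotic metabolism, −0.22 for the unfolded protein and ATF4 response, 0.18 for class I presentation, −0.10 for angiogenesis and 0.17 for NRF2 targets, with camera adjusted p = 0.116, 0.248, 0.295, 0.408, 0.734, 0.735 and 0.907. The NRF2 targets had a mean of −0.00690. When adjusted over the list alone, 1 checkpoint gene rose and no other member of these lists changed. The leukocyte gene Ptprc had a log2 fold change of 0.66 ± 0.15 (SE; edgeR adjusted p = 0.0543), and Col1a1, Hbb-bs and Pecam1 had 0.33 ± 0.24, 0.54 ± 0.54 and −0.04 ± 0.38 (SE) with no call. The sign of Pecam1 turned with scaling by library totals or upper quartiles, at 0.0706 and 0.0292, and without artemisinin replicate 1 or 2 or model replicate 2 or 3, at 0.253, 0.0192, 0.0612 and 0.0648.

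The FPKM table gave a similar set of genes by another model. Limma's trend test on log2(FPKM + 0.1) called 706 of 14015 genes, 390 higher and 316 lower, and 587 of them were also called from the counts. Fold changes from both tables had a Pearson correlation of 0.960 across genes, which are not independent replicates. Without artemisinin replicate 1, 2 or 3 the FPKM count was 413, 1421 and 405, and without model replicate 1, 2 or 3 it was 18, 140 and 30.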

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

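Limma-voom with library weights and fry's mixed test were chosen after seeing the data, and the other alternatives here were planned. No called gene turned its direction in any of the 17 alternatives of the gene fit. All 682 called genes had separated groups, so leaving out a library could hardly turn a direction, and this says little about their stability. DESeq2, limma-voom, RLE factors and no filter kept 681, 562, 680 and 616 of them. Without artemisinin replicate 1, 2 and 3 the number kept was 260, 630 and 362. Without model replicate 1, 2 and 3 it was 17, 114 and 23. The counts of genes higher and lower moved beyond 1.5 times with DESeq2 (1251 and 1035), library weights (561 and 560), 1 surrogate variable (26 and 6), and an unadjusted p with a 2-fold change (1112 and 554). With a library left out they ranged from 6 to 670 and from 11 to 713. The cause of these moves was not tested. Of 146 genes followed across the settings, the 90 called ones kept their call in 1038 pairs of gene and setting and lost it in 489, and the others gained one in 73. Program lists called went to 0 with an estimated correlation and with fry, and to 13 with the mixed test, which asks for change in either direction and kept 3 of the 4. Cell type lists called went to 0 with an estimated correlation and with fry, and to 8 with the mixed test, which kept 4 of the 11. With a library left out, program lists ranged from 2 to 6 and cell type lists from 9 to 14. The FPKM count of 706 became 461 without a filter on low values, and ranged from 18 to 1421 with a library left out. At these depths, genes with 1 to 3 counts in a group were limited by counting error.

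No pairing of the mice by replicate number was seen in the expression values, which cannot exclude a matching of the mice that the labels do not give. Deviations of same-numbered mice correlated at 0.007, −0.137 and 0.044 for numbers 1, 2 and 3, and none of the 3 artemisinin mice correlated best with the model mouse of its own number. With the replicate block edgeR called 65 genes higher and 63 lower, 121 of them called without it, and the FPKM count was 225. The block called 4 program and 9 cell type lists, and scaling by library totals also called 9 cell type lists.

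Among the genes followed, signs turned only for some that were not called, and the separated groups of the called genes made a turn unlikely. With 1 surrogate variable the log2 fold change was 0.40 for Slc7a11, −0.18 for Gpx4, −0.00891 for Vegfa, 0.19 for Cdkn1a, 0.41 for Pecam1 and −0.22 for Hbb-bs. With library totals Cdkn1a was at 0.0183 and Pecam1 at 0.0706, with upper quartiles Pecam1 was at 0.0292, and with library weights Gpx4 was at −0.0253 and Pecam1 at 0.0140. With a library left out, Slc7a11 ranged from −0.840 to 0.0235, Gpx4 from −0.0823 to 0.341, Mki67 from −0.0143 to 0.592, Cdkn1a from −0.227 to 0.0716 and Pecam1 from −0.514 to 0.253. The cause was not tested.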

Other observations

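The gene ontology terms, the further genes and the tests of explanations in this part were chosen after the results were seen, and the counts over other splits of the mice were planned.

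Some genes known from blood monocytes rose in the artemisinin mice, and no list of monocyte markers was tested. Ccr2, the chemokine receptor by which inflammatory monocytes leave the marrow, rose from 55.9 ± 8.83 to 271.2 ± 44.4 normalised CPM (SD, n = 3 per group; log2 2.28 ± 0.20, SE; edgeR adjusted p = 0.00645). Ms4a6c, F13a1, Vcan and Cx3cr1 rose by log2 values of 1.96, 2.55, 2.75 and 1.06, and the chemokine gene Ccl9 rose from 38.5 ± 1.55 to 154.9 ± 30.8 normalised CPM. Among 3668 gene ontology terms with 10 to 300 tested members camera called 60, 42 higher and 18 lower, and with an estimated correlation it called 0, with a smallest adjusted p of 0.999 and 35 terms at an unadjusted p under 0.05. Monocyte chemotaxis was among the higher terms, with 6 of 28 members risen and a median of 0.63 (camera adjusted p = 8.86e-04; adjusted p = 0.999 with an estimated correlation).

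In the term of epidermal growth factor receptor signalling, also called by camera, 5 of 41 members fell and 1 rose, with a median of −0.36 (camera adjusted p = 0.0102; adjusted p = 0.999 with an estimated correlation). The receptor ligand gene Ereg fell from 19.6 ± 5.21 to 3.93 ± 1.16 normalised CPM (SD, n = 3 per group), and the ligand gene Areg fell 3.81-fold. Fam83a, Shc1 and Erbb3 fell as well, and Adgre4, a myeloid receptor gene, rose. The receptor gene Egfr had a log2 fold change of 0.37 and was not called. Of 17 genes with sialyltransferase activity 4 fell and 0 rose (median −0.30, camera adjusted p = 0.0337; adjusted p = 0.999 with an estimated correlation), among them St8sia6, 10.2-fold, whose log2 fold change was −3.34, and −2.73 and not called without model replicate 1. Gjb1 and Gja3 were the 2 of 12 connexin genes that fell.

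Alveolar type 2 markers were low and neutrophil and smooth muscle markers high in the artemisinin mice, while endothelial and alveolar type 1 markers had medians near 0. A lower share of alveolar type 2 cells alone would raise all other types alike, which the values argue against, since the neutrophil median exceeded the endothelial one by 4.67 (bootstrap 95% interval over members 1.91 to 6.03). Less alveolar tissue in the samples would lower both alveolar types, which the values also argue against, since the type 1 median exceeded the type 2 median by 1.97 (1.54 to 2.35). Both intervals resample correlated markers and do not cover the spread between mice. In artemisinin replicates 1, 2 and 3 the mean neutrophil levels relative to the model mean were 2.54, 3.20 and 5.17 on the log2 scale, against −0.35, 0.03 and 0.46 for endothelium. The type 1 levels were −0.12, 0.30 and −0.67, against −2.30, −1.43 and −2.89 for type 2. A loss of tumour cells, which in mice may carry type 2 markers, stays open: the cell cycle list had a median of −0.21, tumour load is not in the labels, and it cannot be told apart from lower expression per cell or a direct drug effect. Inflow of neutrophils and monocytes also stays open and was not tested.

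Trim12a was the only gene with at most 3 counts in each mouse of 1 group and at least 3 CPM in each mouse of the other. The tests argue against 2 explanations. A lower share of type 2 cells would leave it at no less than the lowest share left for their markers, which was 13.9% for Lamp3, and the upper bound of the share left for Trim12a was 0.416%. This bound covers counting error only, and the 3 artemisinin mice had 0, 0 and 1 counts against 456, 537 and 496 in the model mice. Reads counted to Trim12c instead would raise that gene, and its log2 fold change was −1.39 ± 0.16 (SE). An inherited difference between the mice of the groups is a candidate explanation, and with 1 such gene it cannot be told apart from a drug effect, because every mouse of a group shares the state.

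All 10 splits of the 6 mice into 3 against 3 were fitted, too few for a share under 0.05. The real split gave 331 genes higher and 351 lower, as large as in 1 of 10 splits each, and the highest count in a direction in any other split was 0 by edgeR, with between 161 and 832 genes at an unadjusted p under 0.05. For FPKM it gave 706 genes, again in 1 of 10 splits, and the highest other was 0 by limma, with between 125 and 839 genes at an unadjusted p under 0.05. Camera called 4 program lists in the real split and up to 9 in others, with as many in 9 of 10 splits, and 11 cell type lists against up to 16, with as many in 7 of 10.

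Artemisinin replicate 2 had 79 genes at 3 CPM or more that had at most 3 counts in each of the other 5 libraries, led by the myosin gene Myh8 at 1321 CPM, Serpinb3c at 617 CPM and Krtdap at 540 CPM. Krt4, a keratin of squamous epithelium, had 1133 CPM there and at most 1.24 CPM elsewhere. Whether neighbouring tissue was part of that sample was not given in the sources used here, which leaves the meaning of the skeletal muscle and Smpx values open. Artemisinin replicate 1 stood highest for the cardiac, adipocyte and ciliated lists, at 3.16, 3.59 and 1.79 relative to the model mean on the log2 scale. The tissue content of the other samples was not given either. The meaning of the cardiac, fat, airway and smooth muscle values therefore also stays open. On chromosome 6, 4 of 47 tested genes within 1 Mb of C1rb were called, namely C1rb, its neighbour C1s2, 22.7-fold higher, Pianp and Ptpn6. The complement genes C1ra and C1s1 of the same stretch were not called. On chromosome 7, 2 genes within 1 Mb of Trim12a were called, Trim12a and Trim12c, and 11 were not. Both counts include the centre gene, which was chosen because it was called. Over all tested genes 682 of 15242 were called, and clustering was not tested.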
